A study of Mus musculus with 2 samples.

How the data were processed

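Pre-B cells were taken from the bone marrow of C57BL/6-background mice lacking the recombinase gene Rag1 and carrying an IgM transgene, aged 6 to 14 weeks and of both sexes, per the labels' protocols. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done with an antibody to histone H3 monomethylated at lysine 4 (H3K4me1), beside an input library made without antibody. Per the labels' protocols, each library was made from 1 to 10 ng of DNA, amplified over 18 PCR cycles, cut from a gel at 300 bp (±25 bp) and sequenced as single-end reads of 100 bases on an Illumina instrument. The series held 2 samples, 1 per group, and the labels do not say how many mice went into either.

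Per the submitters' processing notes, Bowtie 0.12.9, HOMER 4.7 and the mouse build mm9 were used. Per the file headers, regions were called with HOMER's findPeaks in its histone style, with the H3K4me1 tags against the input tags. Per the file headers, peaks of 500 bases were searched with tags from both strands and stitched into regions of variable length, with a minimum distance between peaks of 1000 bases and a fragment length of 106 bases. A peak needed at least 26 tags where 12.582 were expected from a uniform genome of 2000 Mb (Poisson threshold 0.001), at most 2 tags were considered per position, and peaks had to be 4-fold over input (Poisson threshold 1e-04), per the file headers. The 4-fold filter over the surrounding 10000 bases removed 0 peaks. The header listed 893752 putative peaks, 2713 removed against input, 2 removed as too clonal and 48130 kept. The last 3 counts add up to 50845, the number of stitched regions that this bookkeeping implies before filtering.

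The deposited table held 6 columns of a BED file. Its score column, as deposited by the authors, is 1 for all 48130 regions and carries no measurement. The tag counts, fold changes and p-values per region that the header's column titles name were not used here. No region could therefore be ranked by signal, and regions were described by position, length and spacing. Positions are printed counting from 1. Lengths start at 501 bases, and the next length in the list is 626 bases, so region lengths near the floor reflect the caller's peak size. The input library entered only through the authors' calling step.

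The choices below were made before the data were examined, except where the closing section says otherwise. With 1 library per group there was no replicate, so no p-value is given, and intervals cover counting error only. Intervals on shares are Wilson intervals at 95%, and treat tags or regions as independent; tags from PCR-amplified libraries without molecular identifiers are not independent molecules. Density per chromosome is regions per Mb between the first and the last region, since no chromosome lengths were used. Regions with a gap of up to 12.5 kb were stitched into domains. Spacing was set beside 1000 random placements of the same regions, without overlap and at least the shortest observed gap of 499 bases apart, within the span of each chromosome. Chromosome Y, with 2 regions, was left out of densities and domains. The placement and neighbour statistics were tested on simulated data. Randomly placed regions gave 1.01 times the domains of 5 or more regions that random placement predicts, and regions built in groups gave 71.3 times. Lengths built with a rank correlation near 0.5 between neighbours gave 0.48. The simulated random regions were placed by the same procedure as the reference. The 1.01 therefore checks the computation only, not whether uniform placement is a fair reference. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

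The naming rule was to give the 10 longest regions, the 10 stitched domains with the most covered bases, and the chromosomes of highest and lowest density. Alternatives covered the length minimum, the longer part of the list, covered bases in place of region numbers, the stitching gap and the random model. Planned results on gene classes, transcription starts, lists of lineage genes and the immunoglobulin loci need gene positions on mm9. A GRCm38.p6 gene table was at hand, but its coordinates belong to another build and were not used, so no gene is assigned to any region here.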

Results

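The mark H3K4me1, monomethylation of histone H3 at lysine 4, is found at enhancers and on the flanks of active promoters. It was mapped in mouse pre-B cells, bone marrow precursors at the stage between heavy-chain and light-chain gene rearrangement. The cells came from Rag1-deficient mice, which cannot rearrange their antigen receptor genes, with an IgM transgene. The data were 1 H3K4me1 library, with its called regions, and 1 input library against which those regions were called. The H3K4me1 library held 50945360 tags, per the file header. The depth of the input library was not given in the sources used here. No spread between replicates could be measured.

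The comparison with input asked where in the genome the pre-B cell chromatin was enriched for H3K4me1. Marked regions numbered 48130 and covered 110.1 Mb of mm9, which is 5.51% of the genome size of 2000 Mb assumed by the caller. That size is below the 2562 Mb between first and last regions, summed over the autosomes and chromosome X. This share is thus not comparable with the shares of chromosome span given below, and the density outside regions also depends on the assumed size. The header put 15701950 tags in peaks, 30.8% of the library (Wilson 95% interval 30.81 to 30.83%). Taking these as the tags of the kept regions, the mean tag density was 142.6 tags per kb inside the regions and 18.6 per kb in the rest of that assumed genome, a ratio of 7.65. The header counts 2713 putative peaks removed against input. Read as stitched regions, these are 5.34% of the 50845 that its bookkeeping implies before filtering. A 500-base window needed 26 tags to be called, 2.07 times the expected number, and a kept region also had to pass the 4-fold filter over input.

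Most H3K4me1 regions were short, and a small part of the list was broad. The median region was 1497 bases long, the middle part of the distribution ran from 813 to 2694 bases (25th and 75th percentiles), and the mean was 2288 bases. The shortest possible length, 501 bases, was shared by 6870 regions (14.3%). At the other end, 4292 regions (8.92%) were at least 5000 bases long and held 34.0% of all covered bases. Regions of at least 10000 bases numbered 1036 (2.15%) and held 13.9% of covered bases, and 127 regions reached 20000 bases. The 4813 longest regions held 36.3% of the covered bases, beside 18.8% in the 24065 shortest.

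**Figure D1:**
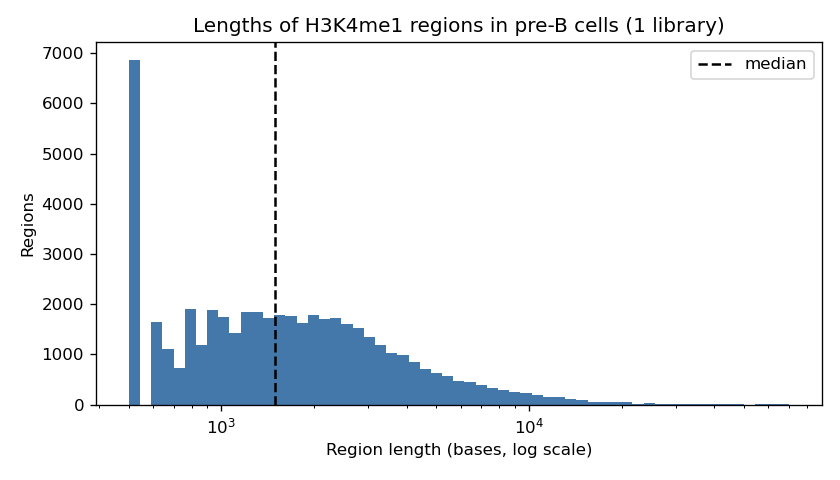
Histogram of the lengths of all 48130 H3K4me1 regions of the pre-B library, with region length in bases on a log axis and the number of regions on the vertical axis. The dashed line is the median of 1497 bases, the spike at the left is the 6870 regions of 501 bases, and the tail runs to 68368 bases.

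The longest region, stitched by the caller, spanned 68.4 kb on chromosome 11, from 118040105 to 118108472 of mm9. The next, on chromosome 7 from 139874636 to 139935374, spanned 60.7 kb, and a region on chromosome 15 from 58856786 to 58912066 spanned 55.3 kb. These were the only 3 regions of at least 50000 bases. A second region on chromosome 15 (74724318 to 74770880) was 46.6 kb long, and regions on chromosome 8 (129337478 to 129382711) and chromosome 16 (95634827 to 95679550) were 45.2 and 44.7 kb long. The region on chromosome 7 from 71037565 to 71081579 was 44.0 kb long. On chromosome 6, a region of 42.5 kb (120504882 to 120547410) lay directly before one of 42.3 kb (120548712 to 120591006). The tenth longest, at 41.2 kb, lay on chromosome 13 from 51824791 to 51865993. Genes at these positions were not analysed here.

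H3K4me1 regions were densest on chromosomes 11 and 19 and sparsest on chromosome X. Over the 19 autosomes the density was 19.9 ± 4.05 regions per Mb of span (mean ± SD over chromosomes, which are not replicates). Chromosome 11 had 29.9 regions per Mb, chromosome 19 had 28.2 and chromosome 17 had 24.9. The sparsest autosomes were chromosome 14, with 15.04 regions per Mb, and chromosome 3, with 15.05. Chromosome 11 was thus 1.99 times as dense as chromosome 14 (counting interval 1.88 to 2.11). These chromosomes were picked as the highest and lowest of the 19 autosomes, which the interval does not take into account. Chromosome X had 1194 regions at 7.42 per Mb, below every autosome and 0.372 times the autosomal mean (counting interval 0.351 to 0.394). Both counting intervals treat regions as independent. Region counts in megabase windows had a variance 20.1 times their mean, so regions were clustered and both intervals are too narrow.

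The same chromosomes stood out by covered bases. Regions covered 7.39% of the span of chromosome 11 and 7.01% of that of chromosome 19, beside 3.18% for chromosome 3, the lowest autosome by this measure, and 1.37% for chromosome X. Median region length differed less among the autosomes, from 1386 bases on chromosome 12 to 1634 on chromosome 11. On chromosome X it was 1198 bases, shorter than on every autosome. Chromosome Y had 2 regions, of 501 and 800 bases, within the first megabase. The input and H3K4me1 cells came from mice of both sexes, per the labels' protocols, and the share of each was not given in the sources used here.

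**Figure D2:**
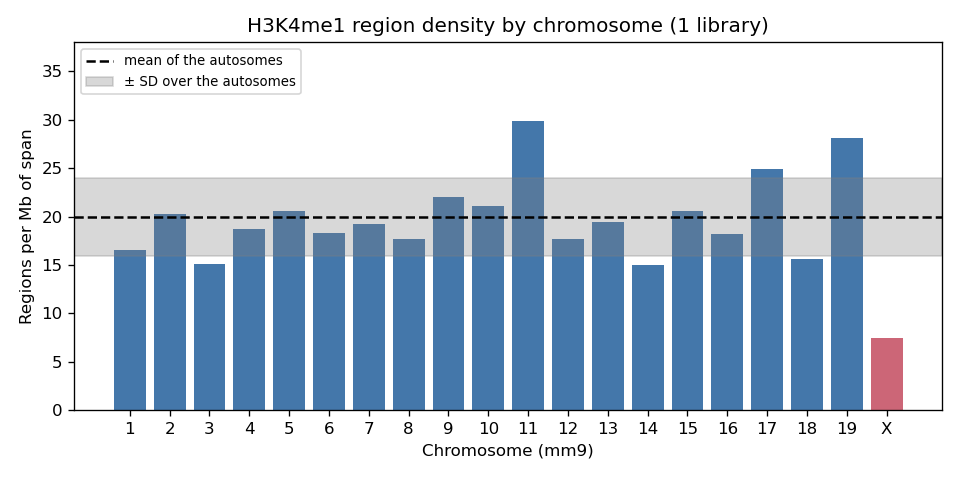
Bars give H3K4me1 regions per Mb between the first and last region of each chromosome in the 1 pre-B library, with the dashed line and grey band showing the mean ± SD over the 19 autosomes (19.9 ± 4.05). Chromosome 11 is highest at 29.9 regions per Mb and chromosome X, drawn in red, is lowest at 7.42; chromosome Y, with 2 regions, is not drawn.

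Marked regions lay close together. The median gap between neighbouring regions was 8.87 kb (25th and 75th percentiles 2.35 and 28.6 kb), and random placement of the same regions in the same spans gave a median of 33.9 kb, ranging from 33.5 to 34.5 kb in 1000 placements. Gaps of up to 12.5 kb made up 57.7% of all gaps, beside 22.3% in the placements. Stitching over such gaps gave 20377 domains, below the lowest placement, which had 37099. Of these domains, 10035 held a single region and 2299 held 5 or more. Those 2299 domains held 17514 regions, 36.4% of the total, and had a median span of 40.9 kb, of which a median of 42.4% was covered. Random placement gave 111.4 such domains on average and at most 154, so the observed number was 20.6 times the random mean. This ratio depended on the stitching gap. It was 229.2 at a gap of up to 5 kb (875 domains against a random mean of 3.82) and 3.63 at up to 25 kb (2943 against 810.8). Placing regions only outside region-free gaps over 100 kb, an alternative chosen after seeing the data, raised the random mean to 2159 and lowered that ratio to 1.06, with at most 2265 such domains in any placement. Those gaps were taken from the same list of regions.

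The domain with the most covered bases lay on chromosome 9, from 32278271 to 32558327, where 34 regions covered 151.3 kb of 280.1 kb. The second lay on chromosome 6, from 120478864 to 120667718, where 27 regions covered 142.4 kb, or 75.4% of the domain. It contained both of the long adjacent regions named above. On chromosome 8, 24 regions covered 125.8 kb from 129207073 to 129411435, and 34 regions covered 123.3 kb from 73177213 to 73431301. A domain on chromosome 7, from 71029272 to 71205959, held 21 regions over 125.0 kb. The other 5 of the 10 covered between 109.5 and 118.0 kb each. They lay on chromosome 2 (169945976 to 170177675), chromosome 11 (22654961 to 22857193), chromosome 14 (122270907 to 122479164), chromosome 5 (122579120 to 122769185) and chromosome 17 (29137623 to 29323870). Only 4 of the 10 longest regions fell within these 10 domains. The 203 domains with the most covered bases, the top 1% of domains, held 11.9% of all covered bases.

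**Figure D3:**
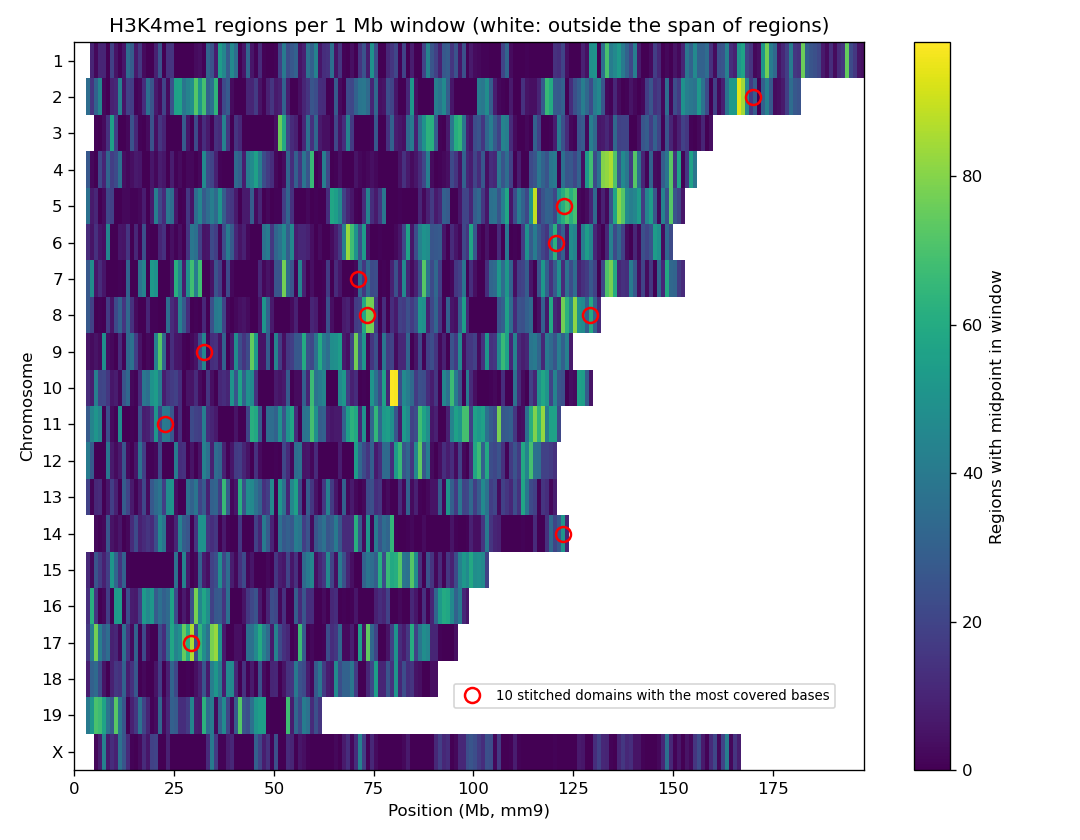
Map of H3K4me1 region density in the 1 pre-B library, with chromosomes in rows, mm9 position in Mb along the horizontal axis and colour giving the number of region midpoints per 1 Mb window. Red circles mark the 10 stitched domains with the most covered bases, which lie on 9 chromosomes, and the row of chromosome X is darker than the autosomes.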

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

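All tests in this part, the one on regions of at least 2000 bases included, were chosen after seeing the data. Each region's name ends in a number that the planned comparisons did not use, and these numbers were looked at for that reason. The highest number on each chromosome, summed over chromosomes, came to 893263, which is 99.9% of the 893752 putative peaks in the header, so they appear to index putative peaks within each chromosome. On that reading, chromosome X had 11.7 putative peaks per kept region, and the autosomes had 18.7 ± 0.779 (mean ± SD over 19 chromosomes, range 17.2 to 19.9). Numbers on chromosome Y reached 368 for 2 kept regions.

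Chromosome X had 0.372 times the mean autosomal density of H3K4me1 regions. The deficit was not confined to the shortest regions: the ratio was lower, not higher, for regions of at least 2000 bases, at 0.256. Region lengths themselves come from stitched peaks that passed the calling threshold. A threshold effect that also shortens longer regions therefore stays open. So does a lower tag depth on chromosome X. Putative peaks per covered kb came to 6.32 on chromosome X and to 7.82 to 8.55 on the autosomes, but this value restates the region numbers that raised the question and is no independent measure of depth. Fewer X copies in male cells, or weaker marking of X chromatin, may lie behind it; the labels give no sex share, and no biological explanation was tested.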

How the results depend on the processing

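Alternatives on joined regions, on spans without long gaps, on regions of at least 2000 bases for chromosome X and on neighbouring lengths were chosen after seeing the data. The list of 48130 regions fell to 32543 of at least 1000 bases, 24056 above the median length and 18050 of at least 2000 bases, by construction. The density of chromosome X over the autosomal mean stayed below 1 under each alternative run: 0.329 for regions of at least 1000 bases, 0.286 for those above the median length, 0.256 for at least 2000 bases, 0.298 by covered bases and 0.521 without gaps over 3 Mb (main value 0.372). Chromosome 11 stayed above chromosome 14 under its alternatives, by 1.66 to 2.26 times. Stitching over 25 kb gave 13352 domains in place of 20377, stitching over 5 kb gave 29726, and regions above the median length gave 13948. Domains of 5 or more regions over random placement came to 229.2 at a gap of 5 kb, 3.63 at 25 kb, 113.9 for regions above the median length and 53.5 after joining regions under 2.5 kb apart (main value 20.6). The ratio was 1.02 with gaps shuffled within chromosomes, which keeps the gap sizes by construction. It was 1.06 in spans without gaps over 100 kb, and 4.66 there at a gap of 5 kb. With regions under 2.5 kb apart joined first, it was 1.32 in those spans, 6.03 there at a gap of 5 kb, and 535.1 in the full spans at a gap of 5 kb. The largest ratios reflect small random means, since the observed numbers were below the main 2299. The 535.1 set 61 domains against a random mean of 0.114. The 229.2 and 113.9 set 875 and 678 domains against 3.82 and 5.96. The planned comparisons by score could not be run because the score is constant, and those on genes were not run because no mm9 annotation was used. Depth per region was not used here, so which regions lie near the calling thresholds is unknown.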

Other observations

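Regions were unevenly spread over megabase windows of the pre-B genome. Of 2579 windows of 1 Mb within the spans, 490 (19.0%) held no region midpoint and the 257 densest windows held 32.1% of all regions. The densest windows, chosen after their values were seen, were 2 adjacent ones on chromosome 10 (79000001 to 80000000 and 80000001 to 81000000 of mm9), with 98 and 97 regions against a median of 13 per window. Windows on chromosome 2 (166000001 to 167000000), chromosome 5 (115000001 to 116000000) and chromosome 17 (29000001 to 30000000) followed with 94, 89 and 86. Chromosome X had the highest share of empty windows, 62 of 162 (38.3%), and chromosome 9 the lowest, 6 of 122 (4.92%). The longest region-free stretches, also chosen after the fact, were 11.9 Mb on chromosome 15 (13323595 to 25199110) and 10.1 Mb on chromosome X (23298599 to 33427941). Assembly gaps and unmappable sequence within these stretches were not analysed here.

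The most isolated regions were the shortest. Regions whose nearest neighbour lay within 2.5 kb had a median length of 1541 bases and 12.3% of them had the shortest length. Medians were 1581 bases at a nearest gap of 2.5 to 12.5 kb and 1349 at 12.5 to 50 kb, so length did not fall steadily with isolation. The 2270 regions with no neighbour within 50 kb had a median of 1062 bases and 22.8% at the shortest length.

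The excess of multi-region domains was weighed against 2 explanations, with tests that, except the gap shuffle, were added after seeing the data. Splitting of broad stretches by the caller, over gaps under 2.5 kb, is argued against as the whole source at a gap of 5 kb. At 12.5 kb it stays open. Joining such regions cut the domains of 5 or more from 2299 to 978. The random mean fell from 111.4 to 18.3, so the ratio was 53.5. That ratio cannot decide, because long region-free gaps raise it too: without gaps over 100 kb the unjoined ratio was only 1.06. Spans without the 3657 gaps over 100 kb leave 823.9 of 2562 Mb. There the joined regions gave 1.32 times the random mean (978 against at most 807). These spans were cut at gaps of the tested list, so the 1.32 does not decide either. At a gap of 5 kb the joined regions gave 6.03 times the random mean there (61 against at most 21). Whether region-free stretches set the excess stays open at a gap of 12.5 kb, because the gap shuffle (ratio 1.02) keeps every gap size and the reduced spans (ratio 1.06, 2299 against at most 2265) are cut at gaps of the tested list itself; at a gap of 5 kb the reduced spans left 875 domains against 187.7, a ratio of 4.66, so stretches over 100 kb do not account for that clustering.

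Neighbouring regions were only slightly alike in length, with a Spearman rank correlation of 0.053 across neighbours of this library, which are not independent replicates. Shuffling lengths within chromosomes gave at most 0.017 in 100 shuffles, which argues against length differences between chromosomes. The rank correlation was 0.080 among regions longer than the shortest length, and 0.053 for those over 10 kb apart. Over all regions it was 0.049 for neighbours over 10 kb apart (at most 0.022 in the shuffles) and 0.026 for those over 50 kb apart, where the highest shuffle also gave 0.026. The bound set beforehand for splitting by the caller was 0.05 at over 10 kb, so near the 0.053 over all neighbours that it could hardly decide. The 0.049 over all regions fell just below it, and the 0.053 among regions longer than the shortest length just above. Both values for neighbours over 10 kb apart exceeded every shuffle (at most 0.022 and 0.024). Part of the likeness thus lay beyond short gaps, but splitting as a source stays open.

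The rows of the region list follow length closely but not exactly (rank correlation of -0.97 between row number and length), and the file header does not say what sets their order.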
